A study of Zea mays and Arabidopsis thaliana with 3 samples.

How the data were processed

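Chromatin from maize B73 leaf nuclei was digested with MNase and sequenced, with 1 library at 100 U and 1 at 900 U. Per the labels' protocols, fragments of about 150 bp were recovered from native nuclei, and libraries were made with a NEBNext Ultra II kit and sequenced on a NovaSeq instrument. The submitters' processing notes name fastp 0.20.0, Bowtie2, SAMtools 1.5, MACS2, ChIPseeker and deepTools, and the build B73 RefGen_v4. The role of each tool, the program that called the nucleosome positions, its threshold and the scaling between libraries are not given in the sources used here.

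The authors deposited 1 position list per library, without a header. In both lists every call is 140 bp wide with its centre 70 bp from the start, 2 calls of one library are never closer than 100 bp, and most centres lie on a 10-bp grid. The names and units of the fifth and sixth columns are not given in the sources used here. The fifth, never negative and a multiple of 8 in more than 99.9% of calls, was read as a signal height as deposited by the authors, from its place and values; this is an inference, how the authors scaled it is not given, and every filter by height and every test of a calling floor depends on it. The sixth was used as deposited by the authors, as a score of unknown meaning. As the scaling of the heights between libraries is unknown, heights were ranked, filtered and summarised only within a library, and levels were not compared between libraries. Read depth is unknown, so the number of calls is the only measure of depth, at 4419279 in the light digest and 4137218 in the heavy digest. A shallower library or a stricter threshold gives fewer calls, and a position under the threshold is not listed.

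Each call was represented by its centre, and chromosomes were taken to end at the last called base. Calls were counted per chromosome, in 1-Mb bins, in the outer 20% at each end, in the middle 20% and in 1-kb windows. Distances between neighbouring centres were summarised up to 500 bp. Distances between all pairs were counted in steps of 10 bp, and a sine and cosine with a quadratic trend were fitted between 250 and 1250 bp for periods from 150 to 230 bp. A call was shared when the other library had a centre within 20 bp, and chance was taken from 10 fixed-seed moves of 1 to 10 kb. Counts carry exact Poisson intervals, shares exact Clopper-Pearson intervals, and ratios of 2 counts the interval of the matching binomial share, all at 95%. These cover counting error only. With 1 library per digest no p-value was computed, and the spread over 10 chromosomes describes these libraries and not replicates.

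Comparisons, alternatives and the rule for named regions were fixed before the data were examined: the 5 bins of 1 Mb with the highest and the 5 with the lowest heavy-to-light ratio among bins with at least 1000 calls in each library. The fit of periodicity, the windows called in 1 digest only and the alternatives that leave out chromosome 6 or bins with few calls were added afterwards. The rule for named genes, 14 gene lists, profiles around gene starts, gene features and base composition needed a genome or annotation of the same build. The gene table used here is of assembly NAM 5.0 and reaches past the last called base on 9 of 10 chromosomes, so none of its coordinates were applied and these parts were not run. Alternatives were the tallest 50% of each library, thinning of the light calls to the heavy number, a width limit, other distance limits, bin sizes and chromosome parts, and their effect is given in the closing section.

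Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots. The functions were tested on simulated calls over 10 chromosomes. Repeat lengths of 175 and 190 bp were recovered within 2 bp, and random calls at least 100 bp apart gave an amplitude of 0.217%. A planted shared share of 30% was recovered as 29.9% after correction for chance matches, a correction not made for the shares reported below. A planted ends-to-middle ratio of 0.8 was recovered as 0.807.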

Results

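The series compared light and heavy digestion of maize chromatin by micrococcal nuclease (MNase), an enzyme that cuts the DNA between nucleosomes and, with more enzyme, also trims and removes less protected particles. Nuclei came from leaves of 10-day-old seedlings of B73, the inbred line used as the maize reference, with tissue from 10 plants collected per the labels. Native nuclei were digested with 100 U of MNase (the light digest) or 900 U (the heavy digest), fragments of about 150 bp were recovered, and 1 library was sequenced from each. The question was which nucleosome positions are recovered under each condition. The deposited data for each library were a list of nucleosome positions on chromosomes 1 to 10, each 140 bp wide. An Arabidopsis library made with 20 U was not analysed here. With 1 library per digest there was no replicate check and no test between digests. Intervals are 95% intervals that cover counting error only, and neighbouring calls are not independent. The number of reads behind the calls is unknown from these files.

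The heavy digest gave fewer nucleosome calls than the light digest on each of the 10 chromosomes. The light digest gave 4419279 calls (exact Poisson interval 4415160 to 4423401) and the heavy digest 4137218 (4133232 to 4141207). The heavy-to-light ratio was 0.936 (0.935 to 0.937), and per chromosome it ran from 0.925 on chromosome 5 to 0.944 on chromosome 4. Merged light calls covered 609 Mb, or 28.9% of the span of 2106 Mb up to the last called base of each chromosome, and merged heavy calls covered 569 Mb, or 27.0%. Density was 2098 calls per Mb in the light digest and 1964 per Mb in the heavy digest. A difference in sequencing depth or in the calling threshold between the libraries would also change these totals.

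The shortfall of the heavy digest was larger towards the chromosome ends, which in maize are the gene-rich parts of the chromosome arms. In the outer 20% at each end, density was 2036 calls per Mb in the light digest and 1806 per Mb in the heavy digest, a ratio of 0.887 (0.885 to 0.889). In the middle 20% it was 2189 and 2138 calls per Mb, a ratio of 0.977 (0.974 to 0.980). The ratio at the ends divided by that in the middle was 0.908, and it was below 1 on all 10 chromosomes. It ranged from 0.871 on chromosome 5 to 0.971 on chromosome 6 (mean 0.912 ± 0.029, SD over n = 10 chromosomes, which are not replicates). The light digest itself had fewer calls at the ends than in the middle (density ratio 0.930), and the heavy digest more so (0.845). Along 20 equal parts of relative chromosome length, the summed ratio was 0.857 in the first part, 1.00 in the seventh and 0.824 in the last. On chromosome 6 only the far end showed the shortfall. There parts 1 to 4 had ratios of 0.973, 1.12, 0.976 and 0.998, above its middle ratio of 0.952. Parts 17 to 20 had 0.870, 0.853, 0.851 and 0.825. The middle 20% is defined by length and does not mark the centromeres.

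**Figure D1:**
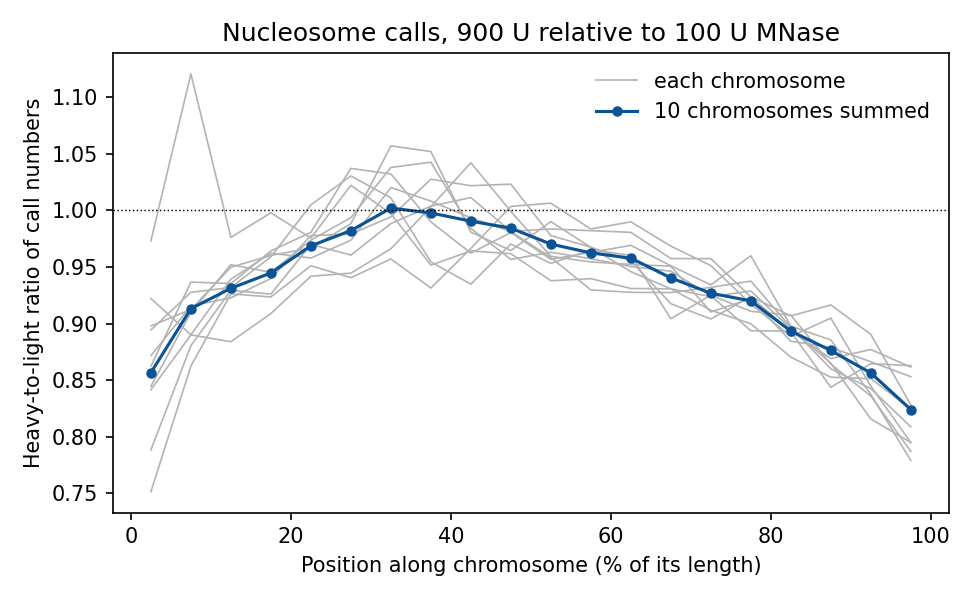
Ratio of heavy-digest (900 U) to light-digest (100 U) nucleosome calls in 20 equal parts of relative chromosome length (x axis, percent of length). Grey lines are the 10 chromosomes and the blue line is their sum, which falls from 1.00 in the seventh part to 0.857 at one end and 0.824 at the other; the single grey peak of 1.12 belongs to chromosome 6.

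Among 2098 bins of 1 Mb with at least 1000 calls in both libraries, the median heavy-to-light ratio was 0.942, with the 5th and 95th percentiles at 0.803 and 1.04. The ratio was above 1 in 347 bins (16.5%), a share that depends on the calls kept. It was 53.5% with the light calls thinned at random to the heavy number. With the tallest 50% of each library, which leaves the ratio of total calls as it was, it was 31.8%. The lowest bin lay on chromosome 5 between 1000001 and 2000000 (B73 RefGen_v4), with 2073 light and 1244 heavy calls, a ratio of 0.600 (0.559 to 0.644). Chromosome 5 between 3000001 and 4000000 had a ratio of 0.632 (0.586 to 0.682), from 1747 light and 1104 heavy calls. The next lowest bins were on chromosome 10 between 149000001 and 150000000 (0.660), chromosome 2 between 2000001 and 3000000 (0.664) and chromosome 7 between 179000001 and 180000000 (0.687). Of the 105 bins in the lowest 5%, 88 (83.8%) lay within 20 Mb of a chromosome end, against 19.0% of the ranked bins.

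At the opposite extreme, 3 of the 5 bins in which the heavy digest most exceeded the light digest lay on chromosome 6. The highest ratio was on chromosome 6 between 10000001 and 11000000, at 1.24 (1.17 to 1.32), from 1880 light and 2330 heavy calls. Chromosome 6 also held the bins between 15000001 and 16000000 (1.14, 1.07 to 1.21) and between 14000001 and 15000000 (1.14, 1.06 to 1.23). The other 2 of the 5 highest were on chromosome 2 between 93000001 and 94000000 (1.15, 1.08 to 1.22) and chromosome 7 between 63000001 and 64000000 (1.11, 1.05 to 1.18). Genes in these bins were not named, because the gene table used here belongs to another assembly.

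Neighbouring nucleosomes lay at the same most frequent distance in both digests, but the heavy digest had more long gaps. The most frequent distance between neighbouring centres was 170 bp in both libraries and on each of the 10 chromosomes. Over distances up to 500 bp the median was 210 bp in the light digest (quartiles 160 and 300 bp) and 215 bp in the heavy digest (160 and 310 bp). Most positions lie on a 10-bp grid, so this gap of 5 bp was not resolved, and it was 0 over distances up to 300 bp and 20 bp over distances up to 1000 bp. Distances above 500 bp made up 21.7% of neighbours in the light digest (21.6% to 21.7%) and 25.2% in the heavy digest (25.2% to 25.3%), with the heavy share larger on 10 of 10 chromosomes. Of this difference of 3.57 percentage points, 1.03 remained once the light calls were thinned at random to the heavy number.

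Beyond the first neighbour, regular nucleosome arrays were more visible in the heavy digest. This comparison of distances between all pairs of calls was added after the neighbour distances had been seen. In the heavy digest, the number of pairs of calls, in steps of 10 bp, had local maxima at 170, 370, 570, 750 and 940 bp. In the light digest the peak at 340 bp was followed by weak maxima at 510 bp and beyond. At the first neighbour the contrast ran the other way. The peak at 170 bp was 154% of the mean over 250 to 1250 bp in the light digest and 142% in the heavy digest. The first trough was 87.3% at 260 bp in the light digest and 91.9% at 270 bp in the heavy digest. The fit below starts at 250 bp and so leaves out the 170-bp peak. An oscillation fitted between 250 and 1250 bp had a period of 189 bp and an amplitude of 4.28% of the mean in the heavy digest, against 179 bp and 2.04% in the light digest. Fitted per chromosome, the period was 189.4 ± 0.7 bp in the heavy digest and 178.2 ± 4.0 bp in the light digest (SD over n = 10 chromosomes). The amplitude was 4.27 ± 0.18% and 2.07 ± 0.15%, and both quantities were larger in the heavy digest on 10 of 10 chromosomes. The light period ran from 172 to 183 bp over the chromosomes. Light maxima at 170, 340 and 510 bp lie closer together than the fitted 179 bp, so that period is not a measured repeat length. The heavy maxima are not evenly spaced either, and the first, at 170 bp, lies below the fitted 189 bp. That period too is a fitted value only. The first trough and the peak after it carried much of the light signal. Fitted from 350 bp, the amplitudes were 0.936% in the light digest and 3.58% in the heavy digest, a ratio of 3.83 in place of 2.10.

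**Figure D2:**
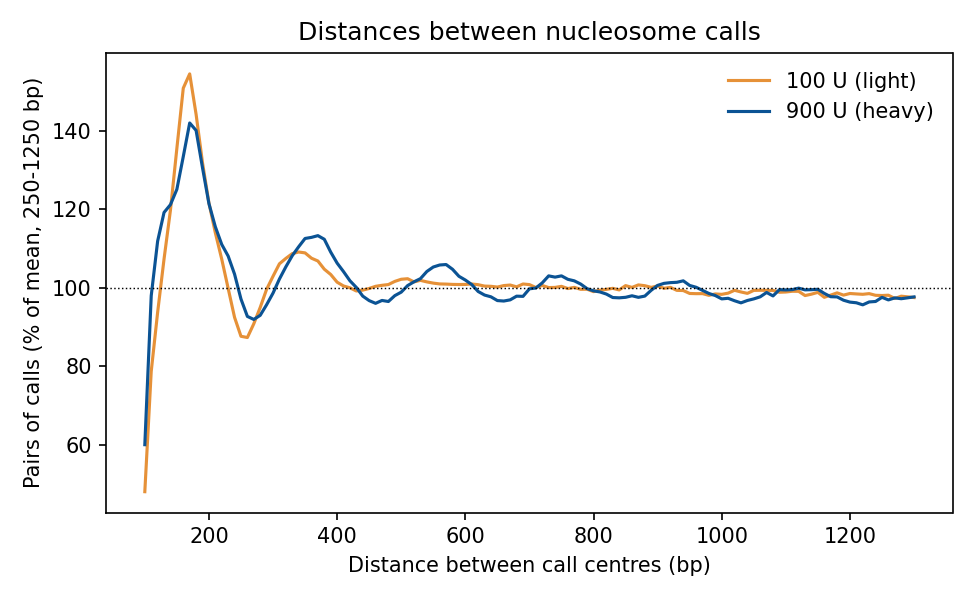
Number of pairs of nucleosome calls (y axis, percent of the mean over 250 to 1250 bp) at each distance between their centres (x axis, bp) in the light digest (100 U, orange) and the heavy digest (900 U, blue). Both curves peak at 170 bp, where the light-digest curve is higher, and the heavy-digest curve has further peaks at 370, 570, 750 and 940 bp.

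About 3 in 10 calls of each digest had a call of the other digest within 20 bp, more than chance placement gives. These shares include chance matches. A call centre of the heavy digest lay within 20 bp of 29.3% of light calls (29.2% to 29.3%), and a light centre lay within 20 bp of 31.3% of heavy calls (31.2% to 31.3%), with 1293863 calls shared on each side. When the other library was moved along the chromosomes by 10 offsets of 1 to 10 kb, these shares were 11.5 ± 0.6% and 12.3 ± 0.6% (SD over the offsets). The observed shares were 2.55 times the chance level in both directions. At the chromosome ends 28.3% of light calls (chance 10.8%) and 31.9% of heavy calls (12.2%) were shared, and in the middle 20% the values were 30.1% (12.3%) and 30.8% (12.6%). Requiring only an overlap of at least 50% of both lengths raised the shares to 57.0% and 60.9%, while chance rose to 34.0% and 36.4%.

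Shared positions had a larger value in the fifth column and a smaller one in the last column than positions of 1 digest only. Both columns are unnamed in the files, and reading the fifth as a signal height is an inference from its place and values. Median height in the units of each file was 128 for shared and 112 for unshared calls in both the light and the heavy digest. The last column had medians of 47.4 for shared and 50.0 for unshared light calls, and of 48.7 and 50.6 for heavy calls. Among light calls the shared share was 21.3% in the lowest 25% by height and 55.7% in the top 1%. Among heavy calls it was 21.9% and 68.1%.

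Clusters of nucleosomes seen in the light digest and missing from the heavy one outnumbered the reverse. This count of 1-kb windows was also added after the data had been seen. Of 851001 windows with at least 3 light calls, 35472 (4.17%, exact binomial interval 4.13% to 4.21%) had 0 heavy calls. Of 768934 windows with at least 3 heavy calls, 14438 (1.88%, 1.85% to 1.91%) had 0 light calls. The ratio of these numbers was 2.46 (2.41 to 2.51), and it lay between 2.25 and 2.79 on the 10 chromosomes. With the heavy calls moved along the chromosomes, windows of both kinds were more numerous, at 111297 light-only and 90783 heavy-only on average, and their ratio was 1.24 ± 0.07 (SD over 10 offsets). With the light calls thinned at random to the heavy number it was 1.64. The excess was larger for denser clusters, at 19548 against 3915 windows with at least 4 calls (ratio 4.99) and 8294 against 838 with at least 5 (9.90). These ratios were 2.86 and 4.85 after thinning. With all light calls kept and the heavy calls moved they were 1.53 ± 0.18 and 1.97 ± 0.39. The moved ratios, like the 1.24 above, are thus to be set against 2.46, 4.99 and 9.90 and not against the thinned values. At the chromosome ends light-only windows outnumbered heavy-only windows 17740 to 5441 (3.26, 3.16 to 3.36), and in the middle 20% 5515 to 2916 (1.89, 1.81 to 1.98). A window with 0 calls holds no position that passed the authors' calling, which does not show that it lacked nucleosomes.

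**Figure D3:**
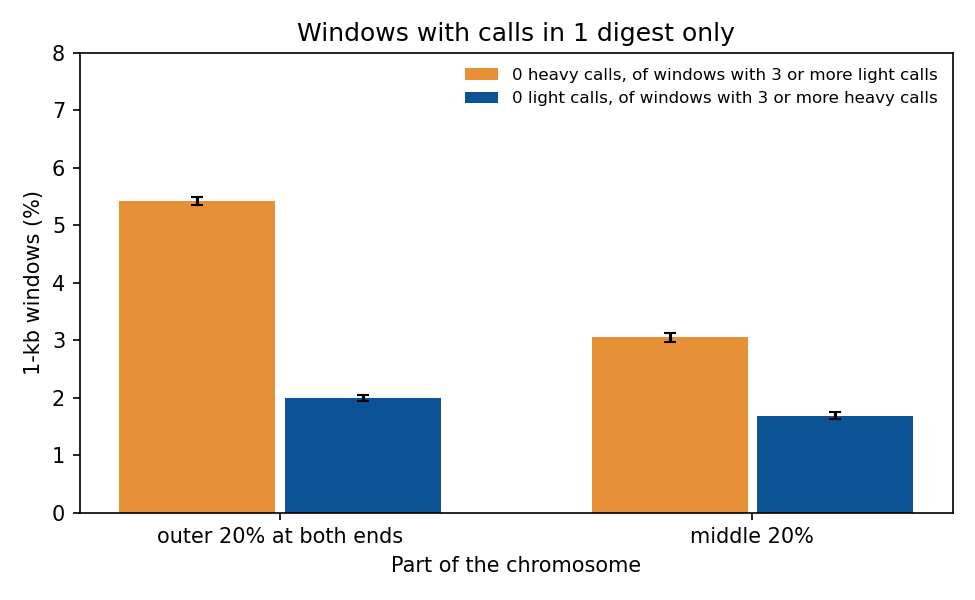
Percent of 1-kb windows with at least 3 calls in one digest that had 0 calls in the other (y axis), for the outer 20% at both ends and the middle 20% of the chromosomes; orange is light-only, blue is heavy-only, and bars carry exact 95% binomial intervals. Light-only windows made up 5.42% at the ends and 3.05% in the middle, and heavy-only windows 2.00% and 1.68%.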

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

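Apart from the share of bins with a heavy-to-light ratio above 1, no difference between the digests changed sign under the alternatives tried. Thinning took that share past 50%. The difference in median neighbour distance and, with thinning, those in the number of calls and in the shared share went to none. The median difference was 0 bp over distances up to 300 bp, 20 bp up to 1000 bp and 10 bp among the tallest 50% of calls in each library. With those tallest calls, distances above 500 bp differed by 3.96 percentage points, 23.7% of light and 25.3% of heavy calls were shared (chance 5.88% and 6.27%), the ends-over-middle ratio was 0.835, 31.8% of bins had a heavy-to-light ratio above 1, and the ratio of light-only to heavy-only windows was 2.13. With light calls thinned to the heavy number, the ratio of calls was 1 by construction, and so the share of bins above 1 went from a minority of 16.5% to 53.5%, distances above 500 bp differed by 1.03 points, 29.3% of light and of heavy calls were shared, and the window ratio was 1.64; the ends-over-middle ratio stayed at 0.907. Shared shares of light and heavy calls were 19.6% and 20.9% within 10 bp, 43.6% and 46.6% within 40 bp, and 57.0% and 60.9% by overlap of at least 50% of both lengths, with chance at 6.81% and 7.28%, 20.9% and 22.3%, and 34.0% and 36.4%. Bins of 500 kb put 21.1% above 1. The window ratio was 4.99 with at least 4 calls, and the ratio of heavy to light amplitude was 3.83 when fitted from 350 bp. The cause of these shifts was not tested. The other 20 of 43 alternative values stayed within the counting interval or 1 SD over chromosomes, but 8 of these were fixed in advance, since the width limit removed 0 calls and keeping 50% of each library leaves their ratio as it was, and 4 more came from random thinning, which changes those values only by sampling. The ends-over-middle ratio was 0.903 without chromosome 6, an alternative chosen after the data were seen. Alternatives on gene starts, gene features, base composition and gene lists were not run, because no genome or annotation of the build was used here. No paired analysis was possible because each digest has 1 library. Unknown read depth limits what a missing call shows.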

Other observations

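The longest stretches without calls were nearly the same in both digests and lay mostly on chromosome 6. The longest ran for 1198 kb in the light digest and 1192 kb in the heavy digest, from 11.54 Mb on chromosome 6. Gaps of 626 and 628 kb followed from 12.82 Mb, and of 559 and 563 kb from 13.68 Mb, on the same chromosome, whose short arm is known to carry the nucleolus organizer, the tandem array of ribosomal RNA genes. Whether these stretches are that array was not tested. In the 1-Mb bins that hold parts of these stretches, the heavy-to-light ratio of calls was 1.19 from 11 to 12 Mb (828 light and 984 heavy calls) and 1.31 from 12 to 13 Mb (64 and 84). It was 0.974 from 13 to 14 Mb (231 and 225) and 1.14 from 14 to 15 Mb. In the bin before them, from 10 to 11 Mb, it was 1.24, and it was also above 1 from 8 to 10 Mb and from 15 to 20 Mb. Chromosome 9 had a gap of 925 kb in the light digest and 927 kb in the heavy digest from 74.99 Mb, and chromosome 4 one of 509 kb in both from 1.89 Mb.

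With the unnamed column after the centre read as height, the tallest calls of both libraries lay in the same 10-kb windows, on chromosome 2 from 157590001 to 157600000 and on chromosome 1 from 197010001 to 197020000. The tallest call in the first window was 816 times the median height of the light library and 1639 times that of the heavy library, and in the second 968 and 839 times. These windows were chosen after their values were seen. Runs of adjacent 1-kb windows called in the light digest only reached 2 kb or more in 2801 places, against 221 for the heavy digest, and 3 kb or more in 387 against 3. With light calls thinned to the heavy number these counts were 2437 against 392 and 329 against 8. With heavy calls also moved along the chromosome, mean counts of 2 kb or more were 14981 (SD 7109) against 13766.5 (SD 7768). Those of 3 kb or more were 4191 (SD 3486) against 3697 (SD 3411), and the ratios of the mean counts were 1.09 and 1.13. Runs of both kinds were thus fewer than moved calls gave, and only their imbalance was larger. With all calls, the longest light-only run was 6 kb with 23 light calls, on chromosome 10 from 36528001 to 36534000, followed by 5 kb with 24 light calls on chromosome 3 from 49664001 to 49669000.

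The tests below that use height depend on reading that unnamed column as height. The tests of periodicity and the test of a stricter floor were chosen after the results they bear on had been seen, as were the use of the tall windows against calls near the floor and their thinned and moved versions; the other tests below were set out before their values were known. The first pattern is the lower heavy-to-light ratio near chromosome ends. A shallower heavy library or a stricter height floor would remove short calls first. Keeping only the tallest 50% of light calls raised their ends-to-middle density ratio from 0.930 to 0.997. That is away from the heavy value of 0.845 and above the midpoint of 0.888 on 10 of 10 chromosomes. A floor on heights distributed along the chromosomes as in the light library would thus not give this pattern. Heavy heights may be distributed otherwise, and a floor on them was not modelled. With the tallest 50% of both libraries the ends-over-middle ratio was 0.835, further below 1 than with all calls. A floor or lower depth in the heavy library therefore stays open. A hypothesis is that heavy digestion removes whole clusters of accessible nucleosomes, which may be more common near the gene-rich ends. It predicts more emptied windows at the ends than even thinning gives, and the test left this open. Of end windows with at least 3 light calls, 5.42% had 0 heavy calls (5.35% to 5.50%). Middle windows whose heavy calls were thinned to the density of the ends gave 5.24% (5.14% to 5.35%) in a single random thinning. The rule set out beforehand asked for a difference beyond both intervals, which meet only at their edges. They do not cover the variation between thinnings. That thinning kept a fraction of 0.845, which also holds the lower light density at the ends. A control not named in the prediction kept 0.908, the ends-over-middle ratio. It gave 4.15% (4.06% to 4.25%), below the value at the ends as the hypothesis predicts, so the outcome depends on the control. Base composition, which steers where MNase cuts, and any difference between these single libraries other than the enzyme amount stay open and untested.

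The second pattern is the excess of windows called in the light digest only. More light calls explain part of it, since thinning to equal numbers lowered the ratio from 2.46 to 1.64, yet 1.64 leaves an excess, and with at least 4 calls it was 2.86 after thinning. Light calls in light-only windows were shorter than in other windows with at least 3 light calls, with a median height of 112 against 120 (higher on 0 of 10 chromosomes). This met the prediction set out beforehand for calls near the floor, and it goes with such calls taking part. The excess did not rest on the shorter 50% of calls alone. Windows were counted that held at least 3 calls of a library's tallest 50% and no call of any height in the other. Of these, 10562 were light-only and 1542 heavy-only, a ratio of 6.85. With heavy calls moved along the chromosome the ratio was 1.56 (SD 0.208 over 10 moves). With light calls thinned to the heavy number it was 3.79, against 1.25 (SD 0.134) when moved. Moving and thinning do not model a stricter floor or lower depth in the heavy library, so that explanation stays open. The enzyme amount and any other difference between these single libraries stay open and untested.

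The third pattern is the weaker periodicity of the light digest. Short calls that blur the pattern were tested by keeping the tallest 50% of light calls, whose amplitude of 2.61% stayed below the midpoint of 3.16% between the libraries, while the same filter raised the heavy amplitude to 5.87%. Less regular calls at the chromosome ends do not account for it, since in the middle 20% the light amplitude was 2.09% against 4.54% in the heavy digest. A hypothesis is that under light digestion incomplete trimming shifts the recovered fragments, which may smear the centres. An even smear of the light centres would also blunt the first-neighbour peak and trough. Those were sharper in the light digest, with a peak of 154% against 142% in the heavy digest and a trough of 87.3% against 91.9%. These values argue against an even smear in these single libraries. Other effects of trimming stay open, and fragment lengths were not analysed here.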
